A study of Ciona robusta with 8 samples.

How the data were processed

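RNA sequencing was carried out on sorted trunk ventral cells of Ciona robusta, a sea squirt. Trunk ventral cells are the multipotent progenitors of the heart and of pharyngeal muscle in ascidian larvae. Embryos had received CRISPR/Cas9 with a guide RNA (gRNA) against Tcf, a DNA-binding effector of canonical Wnt signalling, or with a control gRNA. Cells were taken at 15 or 18 hours post fertilization (hpf). The sample titles place the 8 libraries in 4 groups of 2, one group for each guide at each time. Per the labels' protocols, 200 to 800 cells were sorted into lysis buffer for each sample, and 250 to 2000 pg of total RNA went into SMART-Seq v4 cDNA synthesis by template switching, followed by an Ovation Ultralow library kit. No molecular identifiers are described in the sources used here, so reads are not independent molecules, and counting intervals and floors cover counting error only. Nothing in the labels says whether the 2 libraries of a group came from separate electroporations or batches of embryos. The p-values therefore measure the spread between these samples, which may be technical.

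The deposited values are read counts per gene model, one table per library, with whole numbers and no normalization. Per the submitters' processing notes, TopHat2 2.0.12 and featureCounts were used. The genome build, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so counts of near-identical or overlapping models could be shared between them. Per the file headers, the replicate numbers of the 2 control libraries at 15 hpf are the reverse of those in their titles. The numbers of the titles were used. The files list the same 15232 models of the KH gene set in the same order, and 227 of them had no count in any library. Library totals ran from 6207795 to 9556959 counts, a ratio of 1.54, so that 1 count equalled 0.105 to 0.161 CPM, the unit of counts scaled to a common library total. All pairs of libraries differed by far more than sampling noise. In a chi-square comparison of counts, the statistic divided by its degrees of freedom was 6.4 in the closest pair. This pair was control replicate 2 and Tcf replicate 1 at 15 hpf, libraries of different guides. Pairs within a group ranged from 8.3 (Tcf at 18 hpf) to 15.7 (control at 18 hpf). No library was treated as a duplicate.

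The files give identifiers of gene models and no gene names, and 0 of the 15232 identifiers matched any of the 21486 genes of the reference table supplied for names, which covers another assembly. Gene symbols, functions and coordinates were therefore not assigned. The 17 lists of pathways and cell type markers that had been fixed before the data were examined could not be applied, and the model of the targeted gene was not identified. Gene models are reported by identifier, at most 2 with higher and 2 with lower values for each comparison. The rule, also fixed before the data were examined, took the largest fitted fold changes among called models for which the libraries of the compared groups did not overlap (within each time or guide for the mean comparisons). In the Tcf comparisons and the interaction it was filled up with the smallest unadjusted p-values, as values and not as calls.

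Counts were analysed as deposited with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Models were kept by filterByExpr with its default minimum count of 10 in at least 2 libraries, and 11970 were tested. Trimmed mean of M-values (TMM) factors scaled the libraries. A model of 4 group means was fitted to all 8 libraries, which share one estimate of the spread because a group holds only 2, leaving 4 residual degrees of freedom before moderation. Contrasts were tested with edgeR's robust quasi-likelihood F test, with Benjamini-Hochberg adjustment over all tested models and calls at an adjusted p under 0.05. The contrasts were Tcf against control at 15 hpf, at 18 hpf and as the mean of both times, the interaction of guide and time, and 18 against 15 hpf in each guide and as the mean of both. Standard errors are the log2 fold change divided by the square root of F. CPM values are scaled by the TMM factors and are given as mean ± SD of 2 libraries. Similarity of libraries was described with log2 CPM (prior count 2). The composition of the libraries was compared with exact two-sided permutation tests of 4 against 4 libraries in scipy 1.17.1, with Benjamini-Hochberg adjustment over 6 tests, chosen after the data had been examined. An exact permutation test of 2 libraries against 2 could not fall below p = 0.333, so single models rest on the model fitted across all genes.

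The tools were tested on simulated data, with counts drawn for 11970 models from the means, dispersions and library sizes of these libraries and 200 models changed by known folds. For the comparison at 15 hpf, edgeR's quasi-likelihood test recovered 4% of 1.5-fold, 28% of 2-fold, 70% of 4-fold and 76% of 8-fold changes, with 3 false calls among 92. For the comparison at 18 hpf it recovered 26% of 2-fold and 72% of 4-fold changes. The shares were 52% and 58% for the mean of both times, and 10% and 46% for the interaction. Each percentage rests on 50 models picked at random anew for each comparison, so differences between comparisons also reflect which models were picked. The shares hold for 200 changed models. With fewer changed models, which were not simulated, the Benjamini-Hochberg adjustment demands smaller p-values, so recovery would be lower.

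Alternatives fixed beforehand were DESeq2's size factors, no filter beyond 1 count, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, the replicate number as a block by the titles and by the file headers, the libraries of a comparison alone, and each library left out in turn. Library totals without scaling factors, a crossed pairing at 18 hpf, a floor of 3 counts per group for large changes over time, and the settings for the sets of rising and falling models were added after seeing the data.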

Results

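The data comprise 8 libraries of bulk RNA sequencing of sorted cardiopharyngeal progenitors, 2 for each of control gRNA at 15 hpf, Tcf gRNA at 15 hpf, control gRNA at 18 hpf and Tcf gRNA at 18 hpf. The control libraries held 6207795 and 7765068 counts at 15 hpf and 9556959 and 6554315 at 18 hpf. The Tcf libraries held 7261574 and 7760462 counts at 15 hpf and 7763508 and 7764525 at 18 hpf. Whether libraries were reduced to a common total before deposit is not given in the sources used here, so these totals are the deposited counts and not known to be the depth of sequencing. Between 87.3% and 95.9% of the 15232 gene models had at least 1 count in a library. The files identify genes by model number only, and values are given by these identifiers.

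Libraries grouped first by time. The first principal component of the 500 most variable models held 69.7% of the variance and placed the 4 libraries of 15 hpf between -37.6 and -21.2 and the 4 of 18 hpf between 27.1 and 33.0. Within each time the guides did not overlap on this component either. It was -37.6 and -35.0 in control and -27.2 and -21.2 in Tcf libraries at 15 hpf, and 32.4 and 33.0 in control and 28.5 and 27.1 in Tcf libraries at 18 hpf, an order that 2 against 2 libraries cannot take below an exact permutation p = 0.333 at each time. Pearson's r of log2 CPM between libraries, computed across genes, averaged 0.963 within a group (4 pairs), 0.964 between guides at the same time (8 pairs) and 0.923 between times (16 pairs). By this mean, libraries of different guides were as alike as libraries of 1 group. The composition of the libraries was compared too. The 100 most abundant models of a library took 36.6% ± 0.3 (SD, n = 4) of the counts at 15 hpf and 32.7% ± 0.3 (SD, n = 4) at 18 hpf, and the single most abundant model 8.88% ± 0.35 and 5.93% ± 0.53 (exact two-sided permutation test, p = 0.029 for each, the smallest that 4 against 4 libraries can give, and adjusted p = 0.086 for each over the 6 composition tests made). The adjusted p could not have fallen below 0.05 over these 6 tests, since no measure can separate the libraries fully by both time and guide. It therefore does not speak against a difference. The ranges of the 2 times did not overlap, at 36.4% to 36.9% against 32.3% to 33.0% for the 100 most abundant models. For the single most abundant model they were 8.48% to 9.22% and 5.24% to 6.5%. Within each guide the order was the same. Between guides the share of the 100 most abundant models was 34.7% ± 2.5 in control and 34.6% ± 2.0 in Tcf libraries (n = 4 each, exact permutation p = 0.86, adjusted p = 0.86).

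**Figure D1:**
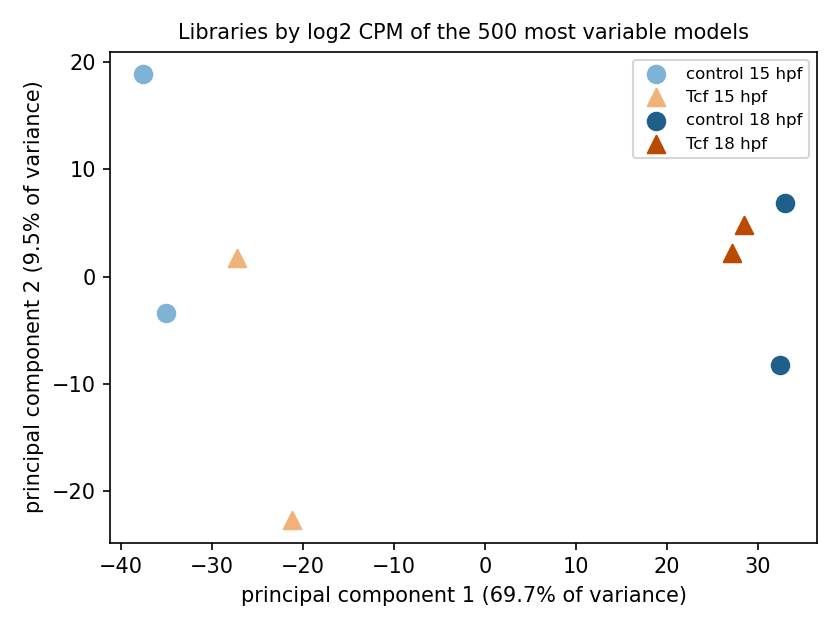
Principal components 1 and 2 (arbitrary units) of log2 CPM over the 500 most variable gene models; each point is 1 library, circles are control and triangles Tcf gRNA, with 2 libraries per group. Component 1, with 69.7% of the variance, separates the libraries of 15 hpf (-37.6 to -21.2) from those of 18 hpf (27.1 to 33.0).

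The comparison of Tcf with control gRNA at 15 hpf asked which transcripts differ in the earlier progenitors when Tcf is targeted. The sources used here do not pair the identifiers with names, so the level of the targeted gene itself is not reported. A single model, KH.C6.71, was lower and none was higher. Its level was 264 ± 9.27 CPM in control and 54.0 ± 8.95 CPM in Tcf libraries (SD, n = 2 each), 4.89-fold lower (log2 fold change -2.29, SE 0.18, adjusted p = 0.00024, edgeR's quasi-likelihood test). Behind these values stood 1526 and 2007 counts in the control libraries and 335 and 438 in the Tcf libraries. KH.C2.469, with 95.1 ± 12.5 CPM in control and 25.4 ± 5.94 CPM in Tcf libraries, had a log2 fold change of -1.90 (SE 0.28) and did not pass the threshold (adjusted p = 0.0739), though it passed in 7 of 17 settings (range over alternatives 4.68e-07 to 0.385). Among these were the fits without control replicate 1 or 2 at 18 hpf (adjusted p = 0.0475 and 0.0329) and without Tcf replicate 1 at 15 hpf (0.0382). Nor did the models with the smallest p among those with higher values. KH.C1.222 had 13.1 ± 1.32 CPM in control and 32.6 ± 6.30 CPM in Tcf libraries (log2 fold change 1.32, SE 0.18, adjusted p = 0.0639) and passed in 5 of 17 settings, among them DESeq2 (adjusted p = 8.29e-06), the fit without control replicate 2 at 18 hpf (0.0427) and that without Tcf replicate 2 at 15 hpf (0.0359), in a range up to 0.999 with limma-voom. KH.C9.326 had 20.5 ± 0.0543 and 37.0 ± 4.52 CPM (log2 fold change 0.85, SE 0.15, adjusted p = 0.219). It passed in 1 of 17 settings, with DESeq2 (adjusted p = 0.00987), and had an adjusted p of 0.999 with limma-voom.

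Of the 11970 models tested at 15 hpf, 605 had an unadjusted p under 0.05, against 598 expected by chance. Single libraries of 15 hpf moved this number both ways. It lay well above chance without control replicate 2 and above chance without Tcf replicate 1. Without control replicate 1 or Tcf replicate 2 it lay below chance. Each of these fits leaves a group with a lone library. The number of calls depended on the tool and on single libraries. DESeq2 called 22 models, 14 higher and 8 lower, and limma-voom 4, all lower. Without Tcf replicate 1 at 15 hpf edgeR called 19, of which 17 were higher and 2 lower, so the balance of directions turned round in these 2 settings with the most calls. It called 2 without Tcf replicate 2 at 15 hpf (1 higher), 4 and 6 without control replicates 1 and 2 at 15 hpf (2 and 3 higher), and 3 and 6 without control replicates 1 and 2 at 18 hpf (0 and 2 higher). KH.C6.71 was among the calls under each of the 16 alternatives, with adjusted p from 2.67e-29 to 0.00215.

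At 18 hpf the same question was put to the later progenitors. KH.C6.71 was again the one model called, with 200 ± 20.2 CPM in control and 70.8 ± 14.7 CPM in Tcf libraries (SD, n = 2 each), 2.83-fold lower (log2 fold change -1.50, SE 0.17, adjusted p = 0.0176, edgeR). KH.C4.404 had 5.12 ± 1.64 CPM in control and 0.72 ± 0.487 CPM in Tcf libraries, from 60 and 28 counts against 9 and 3. Its log2 fold change was -2.81 (SE 0.45), and it did not pass the threshold (adjusted p = 0.258). It passed in 2 of 18 settings, with DESeq2 (adjusted p = 0.000124) and without control replicate 2 at 18 hpf (log2 fold change -3.12, adjusted p = 0.0465), in a range of 0.000124 to 1 over its alternatives. Its log2 fold change was -3.73 without Tcf replicate 1 at 18 hpf (adjusted p = 0.583). The models with the smallest p among those with higher values were KH.C9.252 and KH.C3.443. KH.C9.252 had 20.6 ± 2.97 CPM in control and 38.3 ± 0.99 CPM in Tcf libraries (adjusted p = 0.684). It passed in 1 of 18 settings, with DESeq2 (adjusted p = 0.0392), and had an adjusted p of 0.93 with limma-voom. KH.C3.443 had 562 ± 62.7 and 812 ± 38.4 CPM (adjusted p = 0.706). Unadjusted p-values under 0.05 numbered 459, against 598 expected by chance. Single libraries of 18 hpf moved this number both ways. It lay above chance without control replicate 2, and further below chance without control replicate 1 or Tcf replicate 1, in fits that leave a group with a lone library. The call of KH.C6.71 was lost without Tcf replicate 1 at 18 hpf (log2 fold change -1.30, adjusted p = 0.552) and when only the 4 libraries of 18 hpf were fitted (log2 fold change -1.50, adjusted p = 0.108), and over its 17 alternatives the adjusted p ran from 7.01e-12 to 0.552. DESeq2 called 14 models, 1 higher and 13 lower, and edgeR called 6 without control replicate 1 or 2 at 18 hpf (all lower), 2 without control replicate 1 or 2 at 15 hpf (1 higher each) and 0 without Tcf replicate 1 at 18 hpf (286 at an unadjusted p under 0.05).

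Averaged over both times, 2 models were lower in Tcf libraries and none was higher. KH.C6.71 was lower by 3.72-fold (log2 fold change -1.90, SE 0.12, adjusted p = 3.35e-05, edgeR), with all 4 Tcf libraries below all 4 control libraries. KH.C4.404 was lower by 4.79-fold (log2 fold change -2.26, SE 0.26, adjusted p = 0.00927). At 15 hpf it had 115 ± 22.5 CPM in control and 35.0 ± 7.61 CPM in Tcf libraries (SD, n = 2 each), and its level fell with time in both guides. KH.C10.516 and KH.L96.11 had the smallest p among models with higher values and did not pass the threshold (adjusted p = 0.478 and 0.934). KH.C10.516 passed in 1 of 16 settings, with DESeq2 (log2 fold change 3.65, adjusted p = 0.00688), and had an adjusted p of 0.997 with limma-voom. KH.C10.516 had 0 counts in both control libraries at 15 hpf and 24 and 27 in the Tcf libraries, at least 15.9-fold higher when the control group is set to a floor of 3 counts. This bound covers counting error only. The comparison at 15 hpf did not call this model (adjusted p = 0.228, edgeR's quasi-likelihood test), and 1 of 17 settings there did. At 18 hpf it had 113 and 125 counts in control and 237 and 71 in Tcf libraries. The call of KH.C4.404 was lost with limma-voom and quality weights (log2 fold change -2.29, adjusted p = 0.997) and without Tcf replicate 2 at 18 hpf (log2 fold change -2, adjusted p = 0.0699, 1 model called), in a range of 2.69e-11 to 0.997 over its 15 alternatives. DESeq2 called 15 models, 5 higher and 10 lower. Without Tcf replicate 1 at 15 hpf edgeR called 11, of which 8 were higher and 3 lower, and it called 4 each without control replicate 2 at 15 hpf (1 higher) and without control replicate 1 or 2 at 18 hpf (all lower).

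**Figure D2:**
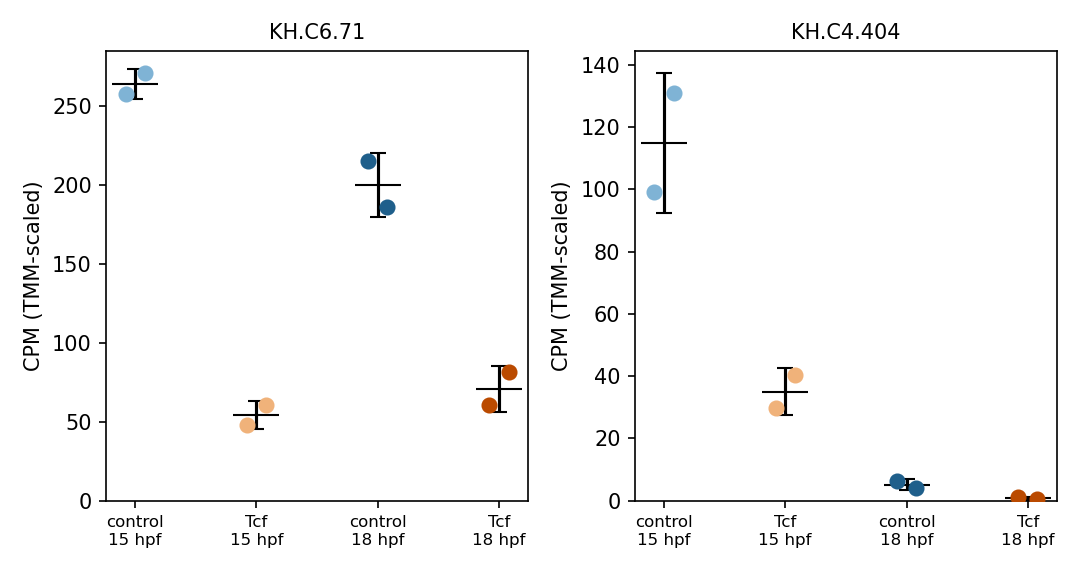
Level in CPM (TMM-scaled, linear axis from 0) of the 2 gene models called in a Tcf comparison, KH.C6.71 and KH.C4.404, by guide and time; coloured points are the 2 libraries of a group, black bars and whiskers their mean and SD. KH.C6.71 falls from 264 to 54.0 CPM at 15 hpf and from 200 to 70.8 CPM at 18 hpf with the Tcf gRNA, and KH.C4.404, low on this axis at 18 hpf, has 6.29 and 3.96 CPM in control and 1.06 and 0.376 CPM in Tcf libraries there.

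Across genes, the effects at 15 and 18 hpf showed no positive relation. Pearson's r of the log2 fold changes was -0.08 and Spearman's rho -0.04 over 11970 models, which are not independent replicates. The 2 comparisons share no library. The median SE of a log2 fold change was 0.35 at 15 hpf and 0.34 at 18 hpf. Such error weakens a correlation over all models, so effects shared by few models are not excluded. The interaction of guide and time tests whether the effect of the Tcf gRNA differed between the times. It called 0 models with edgeR (561 at an unadjusted p under 0.05, 598 expected), 0 with limma-voom and 21 with DESeq2 (3 positive and 18 negative). Leaving out single libraries moved the number under an unadjusted p of 0.05 both ways. Without control replicate 2 at 15 hpf it lay well above chance. It also lay above chance without control replicate 2 at 18 hpf and without Tcf replicate 1 at 15 hpf. Each of these fits leaves a group with a lone library. The smallest adjusted p of the interaction belonged to KH.C1.222 (interaction on the log2 scale -1.78, SE 0.24, adjusted p = 0.104). It passed in 4 of 16 settings, among them the fits without control replicate 1 at 15 hpf (adjusted p = 0.0437) and without Tcf replicate 2 at 15 hpf (0.0406), in a range of 3.27e-06 to 0.484 over its alternatives. KH.C1.222 rose from 13.1 to 213 CPM in control libraries and from 32.6 to 154 CPM in Tcf libraries. KH.C9.326, which rose from 20.5 to 294 CPM in control and from 37.0 to 231 CPM in Tcf libraries, followed with -1.20 (SE 0.20, adjusted p = 0.27). Its interaction passed in 1 of 16 settings, with DESeq2 (adjusted p = 0.00211), and had an adjusted p of 0.995 with limma-voom. With positive values, KH.C3.443 (0.87, SE 0.16, adjusted p = 0.285) and KH.C14.94 (2.66, SE 0.63, adjusted p = 0.722) had the smallest p. KH.C3.443 passed in 1 of 16 settings, with DESeq2 (adjusted p = 0.00736), and had an adjusted p of 0.4 with limma-voom. For KH.C6.71 the interaction was 0.79 (SE 0.24, adjusted p = 0.959). The interaction called 7 and 4 models without control replicates 1 and 2 at 15 hpf, 4 and 1 without Tcf replicates 1 and 2 at 15 hpf, and 1 without control replicate 1 at 18 hpf.

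The change from 15 to 18 hpf was large in both guides. In control libraries 856 models rose and 701 fell, 13.01% of those tested, and 378 of them rose and 119 fell by a fitted change of at least 4-fold (380 and 118 with groups under 3 counts set to 3; edgeR's quasi-likelihood test, adjusted p under 0.05). The models named by their fitted fold had a group without a count, for which the fitted fold sets no rank. KH.S678.4 went from 0 counts in both libraries to 131 and 175 counts, at least 81.9-fold higher against a floor of 3 counts over the group, and KH.C10.516 went from 0 to 113 and 125 counts, at least 63.7-fold higher. KH.C12.217 fell from 32 and 69 counts to 0, at least 41.9-fold lower, and KH.S1528.1 from 11 and 14 counts to 0, at least 10.4-fold lower. The adjusted p of these 4 models lay between 0.000216 and 0.00859. The call of KH.C10.516 was lost with limma-voom (adjusted p = 0.0603, range over alternatives 1.27e-07 to 0.0603) and that of KH.S1528.1 without control replicate 1 at 18 hpf (adjusted p = 0.0536, range 0.00381 to 0.0536). The count of calls fell from 1557 to 931 without control replicate 1 at 15 hpf and to 999 without control replicate 2 at 18 hpf.

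In Tcf libraries 682 models rose and 643 fell with time, 11.07% of those tested, and 263 rose and 82 fell by a fitted change of at least 4-fold (265 and 84 with the floor of 3 counts). KH.C1.238 went from 0 counts in both libraries to 65 and 154, at least 63.5-fold higher, and KH.C4.101 from 0 to 74 and 50, at least 35.9-fold higher (adjusted p = 0.000153 and 0.000369, edgeR). KH.C5.85 fell from 25 and 15 counts to 0, at least 15.3-fold lower (adjusted p = 0.0225). KH.C12.217 fell from 62 and 43 counts to 1 and 0, a ratio of 121 with a 95% counting interval of 21.2 to 4810 (adjusted p = 0.000553). The call of KH.C5.85 was lost without Tcf replicate 1 at 15 hpf (adjusted p = 0.0926), without Tcf replicate 1 at 18 hpf (adjusted p = 0.112) and without Tcf replicate 2 at 18 hpf (adjusted p = 0.102), in a range of 0.00374 to 0.112 over its alternatives. Without any 1 of the 4 Tcf libraries the 1325 calls became 806 or 814 (replicates 1 and 2 at 15 hpf) and 687 or 705 (replicates 1 and 2 at 18 hpf).

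The direction of change over time was mostly shared by the 2 guides; equality of size was not tested by these counts. Across genes, the log2 fold changes had Pearson's r of 0.63 and Spearman's rho of 0.60, and no library is shared. In both guides 488 models rose and 451 fell, against 48.8 and 37.7 expected for independent lists, and 0 were called in opposite directions. Both lists come from 1 fit that shares each model's estimate of spread, so these expected numbers are not a neutral chance level. Of the 618 models called in control libraries alone, 93.9% had the same sign in Tcf libraries, as had 95.3% of the 386 called in Tcf libraries alone in the control libraries.

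**Figure D3:**
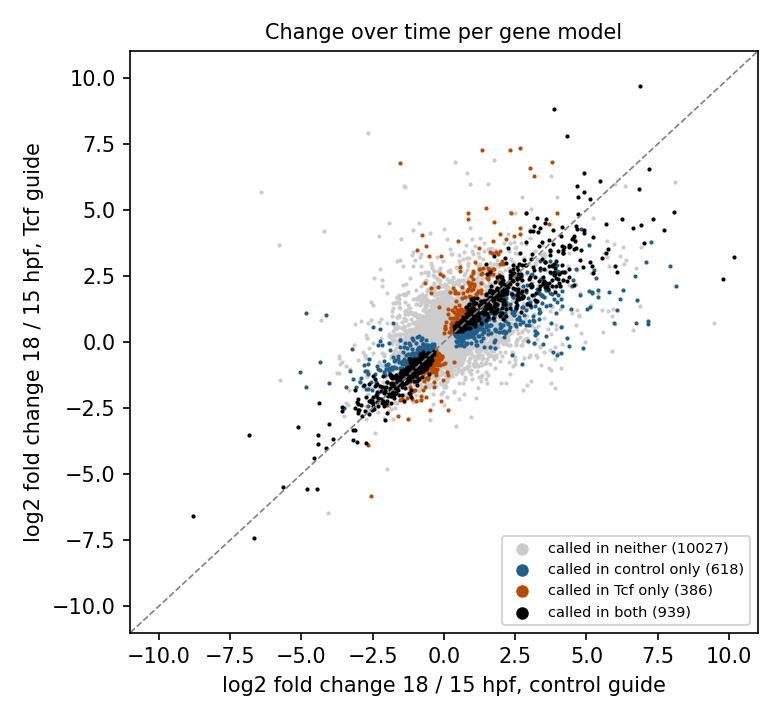
Log2 fold change from 15 to 18 hpf in control (x axis) and Tcf libraries (y axis), 1 point per gene model, 11970 models; colours mark calls at an adjusted p under 0.05, and the dashed line is equality. The 939 models called in both guides lie in the quadrants of equal sign, and 618 and 386 were called in control and in Tcf libraries alone.

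As the mean of both guides, 1458 models rose and 1279 fell, 22.87% of those tested, of which 465 rose and 111 fell by a fitted change of at least 4-fold (465 and 113 with the floor of 3 counts). KH.C1.238 rose from a total of 1 count in the 4 libraries of 15 hpf to between 65 and 154 counts per library at 18 hpf (adjusted p = 6.41e-06, edgeR). KH.C2.14 rose from 0 counts to 79 and 4 counts in control and 16 and 2 in Tcf libraries (adjusted p = 0.021). KH.C12.217 and KH.C5.85 fell to a total of 1 and 0 counts at 18 hpf (adjusted p = 1.27e-05 and 0.00259). The call of KH.C2.14 was lost without control replicate 1 or 2 at 15 hpf (adjusted p = 0.063 and 0.0638), without control replicate 1 at 18 hpf (0.0696), without Tcf replicate 1 at 18 hpf (0.126) and with limma-voom (0.0711), and its adjusted p ran from 0.00265 to 0.126 over the alternatives. The balance of rises and falls depended on the scaling and, in Tcf libraries, on the test and on single libraries. In Tcf libraries falls outnumbered rises without control replicate 1 or 2 at 18 hpf and without Tcf replicate 1 at 15 hpf. These fits leave a group with a lone library. In Tcf libraries DESeq2 called 737 rises and 786 falls, and limma-voom 713 and 747. In control libraries and for the mean of both guides, rises outnumbered falls with both tools. With library totals only, the median of all models moved from 0.019 to 0.138 in control and from 0.045 to 0.2 in Tcf libraries on the log2 scale (from 0.038 to 0.175 for the mean of both guides), and the share of calls that were rises went from 55.0% to 67.8%, from 51.5% to 68.5% and, for the mean of both guides, from 53.3% to 69.1%.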

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

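The sets of rising and falling models, the limit of 4-fold, and the tests on these sets were chosen after the comparisons had been examined; the interaction test itself had been fixed beforehand. Parts of these tests were also changed after their first outcome was known, as stated beside each.

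Among the 2737 models called in the mean time comparison, 233 had an interaction with an unadjusted p under 0.05. Adjusted over these models alone, 1 passed, KH.C1.222 (adjusted p = 0.0238, edgeR), whose log2 rise was 4.03 in control and 2.24 in Tcf libraries. This model already had the smallest interaction p of all tested models, and the value adjusted over the set was not run under other settings. Adjusted over all models, its interaction passed in 4 of 16 settings, with adjusted p from 3.27e-06 (DESeq2) to 0.484 (without Tcf replicate 2 at 18 hpf), among them 0.4 with limma-voom and 0.402 without Tcf replicate 1 at 18 hpf. The set used first held the 1943 models called in the time comparison of either guide and gave 6 such models (smallest adjusted p = 0.0169, 302 at an unadjusted p under 0.05). It was replaced after this outcome was known, because selection within each guide favours models that differ between guides. The mean over guides is free of that, but both tests of a model share its estimate of spread, so selection by a small time p also favours a small interaction p. Neither set therefore has a neutral chance level, and the pass of KH.C1.222 is no evidence beyond its p over all models (adjusted p = 0.104).

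The 465 models that rose at least 4-fold had a median difference in rise of -0.55 on the log2 scale (Tcf minus control, quartiles -1.58 and 0.30), with median rises of 3.24 in control and 2.59 in Tcf libraries. With groups under 3 counts set to 3, which touched 106 of these models, the median difference was -0.42. All 1458 rising models had a median difference of -0.11 (-0.10 with the floor). The 111 models that fell at least 4-fold had a median difference of 0.29 (0.24 with the floor), that is, a smaller fall in Tcf libraries. All 1279 falling models had a median difference of 0.01 (0 with the floor). Limma's camera test with its preset correlation singled out 3 of these sets (adjusted p = 2.1e-05, 0.0027 and 0.0027 for the strongly rising, all rising and strongly falling models). It did not single out all falling models (adjusted p = 0.46). With an estimated correlation none of the 3 passed (adjusted p = 0.098, 0.098 and 0.19), so that the sets were not shown to stand apart from other models. The fry test asks another question, whether a set moves one way on balance, without comparing it with other models, and gave adjusted p = 0.13, 0.13 and 0.37.

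The median Tcf effect of the strongly rising models was 0.42 at 15 hpf and -0.13 at 18 hpf, and that of the strongly falling models 0.04 and 0.31. With the preset correlation, camera gave adjusted p = 0.0016 and 0.0039 for the rising and 0.67 and 0.0039 for the falling models. None of these passed with an estimated correlation (camera adjusted p = 0.2, 0.2, 0.81 and 0.2). Whether 1 time contributed more than the other was not tested. The explanations below for the Tcf libraries at 15 hpf would not produce the value of the falling models at 18 hpf. One library or the scaling is not the whole cause: the median difference stayed between -0.84 (without control replicate 2 at 15 hpf) and -0.44 (without Tcf replicate 2 at 15 hpf), and was -0.52 with library totals only. If the Tcf libraries at 15 hpf came from a slightly later stage, strongly falling models would be lower in them by about 0.35. This value assumes that falling models had passed the same share of their log2 change as rising models. Their median effect was 0.04, beyond a bound of 2 standard errors between libraries (SE 0.15). Equal shares were not tested, and the expected 0.35 was given no error of its own. The median therefore argues only against a later stage with equal shares, and a later stage in general stays open. With 2 libraries per group a smaller contribution is not excluded. The spread between models (SD 0.59) was added to the bound afterwards. It is not the error of a median, and a median without any shift would also lie within it, so the widened bound cannot decide. Reads of 18 hpf libraries in the Tcf libraries at 15 hpf (a mixing share of 3.3%) stay open. Of 120 models, 0% fell short of the bound set beforehand, which first counted in favour. A check added afterwards showed that 2.5% of them could have done so. An effect of the Tcf gRNA was not tested separately from a later stage or from such reads.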

How the results depend on the processing

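With DESeq2's size factors no count of calls moved by 1.5 times. Calls at 15 hpf (1 as reported) became 4 without a filter, 22 with DESeq2, 4 with limma-voom, 2 with library totals only and 2 with the 4 libraries of that time alone; those at 18 hpf (1 as reported) became 14 with DESeq2 and 0 with the 4 libraries alone (563 at an unadjusted p under 0.05). For the mean of both times (2 as reported) they became 4 without a filter, 15 with DESeq2 and 1 with limma-voom, and for the interaction (0 as reported) 1 without a filter and 21 with DESeq2. The counts over time stayed within 1.5 times under these settings. Leaving out each library in turn gave 1 to 19 calls at 15 hpf, 0 to 6 at 18 hpf, 1 to 11 for the mean of both times and 0 to 7 for the interaction, and 931 to 1535, 687 to 1475 and 1997 to 2670 for the change over time in control, in Tcf and as their mean. A group of 1 library lets the filter pass more models (12400 to 12810), and the lone library is assumed to vary like the other groups. The correlation of the Tcf effects at 15 and 18 hpf (-0.08) was -0.01 without a filter and -0.12 to 0.02 with a library left out. Of the alternatives run for single named models, 403 kept their side of the threshold, 14 lost a call, 23 gained one and 0 changed sign. The causes were not tested.

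Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated between -0.17 and 0.06 over the 6 pairs of groups. The number as a block gave 1, 1, 2 and 0 calls by the titles for 15 hpf, 18 hpf, their mean and the interaction, and 2, 1, 3 and 0 by the file headers; over time it gave 1385, 1153 and 2503, and 1407, 1201 and 2545. Because control and Tcf deviations correlated at -0.17 at 18 hpf, the control numbers were also crossed, after seeing the data, which gave 1 call. Tests of the 17 gene lists were not run, since no identifier has a name here. Depth limits low models: 3 counts are 0.314 to 0.483 CPM, and in simulated data edgeR recovered from 10% (interaction) to 52% (Tcf, mean of both times) of 2-fold changes.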

Other observations

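The tests of KH.C6.71, the levels used to describe switching and the comparison of detected models were chosen after the data had been examined; the test over other splits of the libraries was not.

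Few models switched outright with time. In both guides, 11 models were below 0.5 CPM in all 4 libraries of 15 hpf and above 2 CPM in all 4 of 18 hpf, and 2 did the reverse, and all of these were called in the mean time comparison. Between guides, over both times, 0 models switched in either direction by these limits. Thinned to 6207795 counts per library, 13587 ± 234 models (SD, n = 4) were detected at 15 hpf and 14131 ± 330 at 18 hpf (exact two-sided permutation p = 0.057, adjusted p = 0.11 over the 6 composition tests), and 13772 ± 392 in control and 13945 ± 433 in Tcf libraries (exact permutation p = 0.60, adjusted p = 0.86).

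KH.C6.71 was lower in Tcf libraries at both times, with 4 of 4 Tcf libraries below all 4 control libraries. Scaling does not account for it, since its log2 fold change was -1.89 with library totals only, and neither does 1 library, since leaving out each in turn moved it no nearer to 0 than -1.80. The order of the libraries is no test of an effect of the Tcf gRNA, since this model was picked by its p in the same comparison, and such an effect stays open. As a hypothesis, this model may be the transcript of the targeted gene or one that depends on it, which was not tested. A table that pairs KH identifiers with names, or reads over the guide's target site, would decide it, and neither was used here. The counts also do not tell whether a lower count reflects less RNA or edited transcripts that align less well.

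Chance cannot be excluded for the number of 2 models in the mean Tcf comparison. Of 34 splits of the 8 libraries into 4 and 4 with time as a term, 2 gave at least as many, the real one included (2 calls), and the highest other gave 7. That split differs from the real one by exchanging control replicate 1 at 18 hpf and Tcf replicate 1 at 15 hpf, so it still sets 3 of 4 control libraries against 3 of 4 Tcf libraries, and what lies behind its calls was not tested. For the mean time comparison, 1 of 34 splits with guide as a term, the real one, reached the real count of 2723. This count is from the additive model used for the splits, and the highest other gave 1. The other splits mix the times within each side, so a change over time, where there is one, widens their spread and lowers their calls. By themselves the splits therefore cannot exclude chance. Across the guides, which share no library, 939 models were called over time in both and 0 in opposite directions. These values argue against chance for the direction of change of these 939 models.

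Totals of 4 libraries (control replicate 2 and Tcf replicate 2 at 15 hpf, and both Tcf libraries at 18 hpf) lay between 7760462 and 7765068 counts, a range of 4606 or 0.059%, while the other 4 ranged from 6207795 to 9556959. Whether these libraries were subsampled or capped before deposit is not given in the sources used here and was not tested, so their totals are not known to be the depth of sequencing.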
